A study of Homo sapiens with 12 samples.

How the data were processed

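The values analysed were raw read counts per gene, 1 value per gene and library, as deposited by the authors. Per the labels, total RNA was extracted with Trizol and libraries followed standard Illumina protocols. Per the submitters' processing notes, the tools were CASAVA, TopHat2 2.0.14 and DESeq2 and the build was hg19, with no role given for each. The name of the deposited table adds that reads were counted with summarizeOverlaps, a counting function of the GenomicAlignments package. Its counting mode, strand setting and gene model are not given in the sources used here. The counts of genes that overlap another gene, of antisense transcripts and of near-identical paralogs are therefore uncertain, because a shared read may have been dropped or assigned to either gene. Values were checked to be whole numbers with 1 column per library, so replicates had not been pooled. The reads themselves were not analysed here.

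The table held 23459 genes under Entrez Gene identifiers. Of these, 23308 (99.4%) matched a RefSeq gene and were given its symbol, and 151 did not and held 0.839% to 0.991% of the counts of a library. Genes with too few reads for a test were removed with filterByExpr by group, which left 14752 genes. Normalisation used TMM factors, and expression is given as CPM from library sizes scaled by these factors, with the SD over 3 libraries. A count of 3 was taken as the floor of a library, equal to 0.452 to 0.630 CPM at these depths. No coordinates are given, since the annotation at hand was on GRCh38 and not on the authors' build. Exonic overlap between named genes and their neighbours was computed within that annotation (GENCODE, release 29).

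Differential expression was tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with robust estimation, on 1 fit of 4 group means over all 12 libraries. P-values were adjusted by the Benjamini-Hochberg method over the 14752 genes and a gene was called at an adjusted p under 0.05, with no fold threshold. The same fit gave the interaction, defined as the log2 effect of prolactin with R5020 minus its log2 effect without R5020. Its value is the same if the hormones are exchanged. The SE of a log2 fold change was its absolute value divided by the square root of F, and was never taken below the Poisson counting error. Fold changes are fitted values that include a small prior count, so for genes with 1 to 3 counts in a compared group the ratio of counts is given with its 95% counting interval. The common dispersion was 0.000553, a biological coefficient of variation of 2.35%. P-values measure the spread between these libraries, which may be technical, as the labels do not say whether the 3 libraries of a group came from separate cultures. Intervals and floors cover counting error only.

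Before the data were examined, 19 gene lists with 365 genes were fixed from textbook knowledge, and the comparisons, tests, threshold, alternatives and the rule for naming genes were set. The lists were progestin targets, prolactin and STAT5 targets, immediate early genes, ERK feedback genes, estrogen receptor targets, interferon-stimulated genes, G1/S and G2/M cell cycle genes, milk and alveolar differentiation genes, sterol and fatty acid synthesis genes, basal keratins and stem-like markers, luminal markers, ion transport genes of corticosteroid response, growth factor receptors and adaptors, unfolded protein and integrated stress genes, heat shock genes, fibroblast markers, leukocyte and endothelial markers, and housekeeping genes. Some genes are in more than 1 list, so the lists are not independent. HSD11B2 is among progestin targets and ion transport genes, and EGR1 among ERK feedback genes, immediate early genes and STAT5 targets. Each list was compared with all other genes by camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 19 lists of a comparison. Camera was run again with an estimated correlation, and fry tested whether the genes of a list moved, on balance, in 1 direction.

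Genes named by rule were PGR, PRLR, ESR1, STAT5A, STAT5B, FKBP5 and CISH in every comparison. Added to these were the genes with the largest positive and negative log2 fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between the compared groups, for which chance gives 10% of genes with 3 libraries against 3. The limit was 10 genes per direction, or 5 for the combination against vehicle and against prolactin. For each list with a called member, up to 4 members with the smallest adjusted p and up to 2 that did not pass were named. For genes called with both hormones, the 5 per pair of directions with the smallest larger adjusted p were named. Unnamed loci, microRNA and small nucleolar RNA genes were counted and not named. Some genes that met the rule are not reported here, but stay in all counts of called genes and in the list tests.

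The method was tested on simulated data with set changes in 50 genes per fold at the depth and spread of these libraries. For R5020 against vehicle it recovered 56% of changes of 1.25-fold, 82% of 1.5-fold and 90% of 2-fold. For the interaction it recovered 32%, 78% and 80%. Of 14277 unchanged genes, 12 and 7 were called. Overlap between comparisons that share the vehicle libraries was set against 20 simulations in which all groups were unchanged and both comparisons shared the simulated vehicle libraries. Random draws used the seed 20240501.

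Alternatives were DESeq2 size factors or total counts in place of TMM factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a fit on the compared groups alone, an adjusted p under 0.01, and leaving out each library in turn. No sample was left out of the main results. Chosen after the data had been seen were the other form of the quasi-likelihood fit, an assumed coefficient of variation of 10%, leaving out MUC1, and leaving out 1539 genes above 200 reads per kb of transcript. Replicate libraries were compared gene by gene for repeated deposits. Every pair had at least 8 genes that differed beyond sampling noise, and no library was treated as a copy of another. No paired analysis was possible because the titles number the libraries from 01 to 12 and share no replicate number between groups.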

Results

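T47D cells, an established human breast carcinoma line that carries estrogen, progesterone and prolactin receptors, were treated for 6 h and their RNA was sequenced. The 4 groups were vehicle (water and ethanol, the solvents of prolactin and R5020), 10 nM R5020, 100 ng/ml prolactin, and both hormones together, with 3 libraries each and 12 in total. R5020 (promegestone) is a synthetic progestin that activates the progesterone receptor. Prolactin is a pituitary peptide hormone whose receptor signals through JAK2 and the transcription factor STAT5. The title of the series asks how each hormone tunes the genes regulated by the other. That question was addressed with the effect of each hormone alone, its effect in the presence of the other, and the interaction between them.

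Total counts were 4761000, 6643359 and 5100138 in vehicle libraries 1 to 3, 5768890, 5377002 and 5811466 with R5020, 5484447, 5030429 and 4935519 with prolactin, and 5461740, 5151291 and 5620652 with the combination. The 14752 genes with enough reads were tested. The first principal component held 64.4% of the variance and separated the 6 libraries with R5020 from the 6 without it. The second held 10.9% and separated those with prolactin from those without. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.992 to 0.993 within groups and 0.956 to 0.989 between groups. MUC1, which encodes the mucin 1 cell-surface glycoprotein, took the largest share of counts in every library, 0.672% to 2.35%. It varied within the combination group, at 128123, 66101 and 125632 counts in libraries 1 to 3. Vehicle library 2 differed beyond sampling noise from vehicle 1 in 321 genes and from vehicle 3 in 194, against 8 to 131 genes in the other 10 pairs of replicates.

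**Figure D1:**
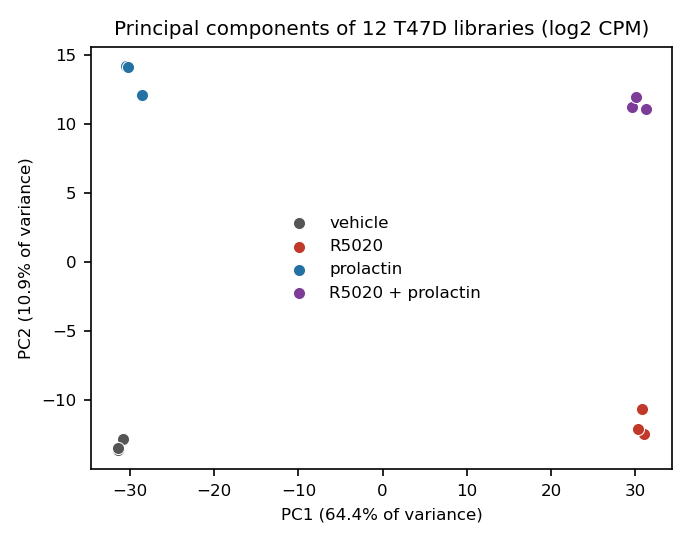
Principal components 1 and 2 of log2 CPM of the 12 libraries, with 1 point per library coloured by treatment and the share of variance on each axis. R5020 separates the libraries along the first component (64.4%) and prolactin along the second (10.9%), and the 3 libraries of each group lie together.

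The first comparison, R5020 against vehicle, asked what the progestin changed alone. KCNC1, a voltage-gated potassium channel, rose 30.3-fold, from 1.60 to 50.6 CPM (log2 fold change 4.92, SE 0.28, n = 3 libraries per group). SCNN1G, the gamma subunit of the epithelial sodium channel, rose 28.6-fold (log2 4.84, SE 0.40). Genes that fell included AMIGO2, a cell adhesion molecule, 19.1-fold lower (log2 -4.25, SE 0.26), the potassium channel gene KCNK5, 10.3-fold lower (log2 -3.37, SE 0.17), and BMPR1B, a receptor for bone morphogenetic proteins, 8.68-fold lower (log2 -3.12, SE 0.25).

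By the edgeR quasi-likelihood test, 6183 genes (41.9%) were called, 3240 higher and 2943 lower. The median fold of called genes was 1.33, and 1019 changed at least 2-fold (602 higher and 417 lower). With total-count scaling 37.7% of the called genes were higher, against 52.4% with TMM. Some genes were nearly absent in 1 group. RP1, a microtubule-associated protein of photoreceptors, had 2 counts in the vehicle libraries and 207 with R5020, a ratio of 105 (95% counting interval 28.8 to 876). DLL4, a Notch ligand, went from 2 counts to 100, a ratio of 50.9 (13.7 to 426). UNC5C, a netrin receptor, fell from 71 counts to 3.

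Of the 28 progestin targets tested, 21 rose, 3 fell and 4 did not pass (22 and 3 when adjusted over the list alone). The list stood above the other genes (camera adjusted p = 1.61e-14; adjusted p = 0.102 with an estimated correlation). NDRG1, a stress-responsive gene of differentiation, rose 13.1-fold, and TSC22D3, which encodes the glucocorticoid-induced leucine zipper, 5.25-fold. KLF4, a zinc finger transcription factor, rose 5.11-fold, and the cochaperone gene FKBP5 rose 1.72-fold, from 268 to 461 CPM (log2 0.78, SE 0.04). ELF5, a transcription factor of alveolar differentiation, was among the 3 that fell (log2 -1.03, SE 0.06). Ion transport genes of corticosteroid response also stood higher, with 8 up, 1 down and 4 not passed of 13, the same counts when adjusted over the list alone (camera adjusted p = 8.31e-06; adjusted p = 0.115 with an estimated correlation). They included HSD11B2, which inactivates cortisol and is also on the progestin list, at 4.41-fold and the ubiquitin ligase NEDD4L at 1.93-fold.

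Interferon-stimulated genes were lower with R5020, with 16 of 22 down, 1 up and 5 not passed (17 down and 1 up when adjusted over the list alone; camera adjusted p = 4.02e-06; adjusted p = 0.258 with an estimated correlation). Examples were the RNA sensor RIGI (log2 -0.98, SE 0.07), IFI44 (log2 -1.48, SE 0.20) and the guanylate-binding protein GBP1 (log2 -1.30, SE 0.20). Estrogen receptor targets moved both ways, 7 up, 12 down and 6 not passed of 25 over all genes and over the list alone, and lay lower as a list (camera adjusted p = 0.0016; adjusted p = 0.301 with an estimated correlation). AREG, an EGF receptor ligand, fell 3.10-fold, the chemokine CXCL12 fell 2.53-fold, and the transcription factor MYB fell 2.45-fold. Of 19 ERK feedback genes, 5 rose, 8 fell and 6 did not pass (5 up and 9 down over the list alone; camera adjusted p = 0.0236; adjusted p = 0.301 with an estimated correlation). PHLDA1 (log2 -1.33, SE 0.06) and the MAP kinase phosphatase DUSP5 (log2 -1.76, SE 0.13) fell, and SPRED2, an inhibitor of Ras signalling, rose (log2 0.46, SE 0.05). Luminal markers were 2 up, 10 down and 8 not passed of 20 (2 and 11 over the list alone; camera adjusted p = 0.0225; adjusted p = 0.485 with an estimated correlation), with the pioneer factor FOXA1 at -0.66 (SE 0.04) and the keratin KRT18 at -0.48 (SE 0.04). Of 24 G2/M cell cycle genes, 10 fell, 14 did not pass and 0 rose, over all genes and over the list alone (camera adjusted p = 0.0113; adjusted p = 0.431 with an estimated correlation), and with total-count scaling 20 fell. The mitotic kinase TTK fell to log2 -0.43 (SE 0.07).

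The other 12 lists were not called for R5020. G1/S cell cycle genes were 9 up and 1 down of 24 (10 and 1 over the list alone; camera adjusted p = 0.0699), with GINS2, part of the replicative helicase, at 0.74 (SE 0.05). Basal keratins and stem-like markers were 4 up and 2 down of 11 (5 and 2 over the list alone; camera adjusted p = 0.0699), with the hyaluronan receptor CD44 2.77-fold higher, from 72.6 to 201 CPM. Immediate early genes were 6 up and 5 down of 22 (0.705), prolactin and STAT5 targets 8 up and 5 down of 22 (0.993), and growth factor receptors and adaptors 9 up and 8 down of 20 (0.623), with the same counts over the list alone. Milk and alveolar differentiation genes were 4 up and 2 down of 11 (4 and 4 over the list alone; 0.993), sterol and fatty acid synthesis genes 9 up and 7 down of 25 (11 and 9; 0.537), and heat shock genes 4 up and 6 down of 19 (5 and 6; 0.705). Unfolded protein and integrated stress genes were 8 up and 1 down of 20 (0.334), fibroblast markers 0 up and 3 down of 4 (0.334), leukocyte and endothelial markers 0 of 5 (0.993) and housekeeping genes 3 up and 0 down of 15 (0.705), again with the same counts over the list alone. For 5 of these lists the signs differed. STAT5 targets had a positive median (0.07) and test and a negative mean (-0.16) that includes SOCS2, with 3 counts in vehicle and 1 with R5020. Growth factor receptors had a negative median (-0.06) with a positive mean (0.10) and test, heat shock genes a positive mean (0.09) with a negative median (-0.06) and test, and milk genes and leukocyte markers positive medians (0.07 and 0.11) and means (0.21 and 0.15) with a negative test. With total-count scaling the medians of the immediate early, sterol and housekeeping lists turned from 0.06, 0.04 and 0.04 to -0.01, -0.03 and -0.02. Calls under that scaling were 5 up and 1 down for G1/S genes, 8 and 11 for sterol genes, 5 and 2 for unfolded protein genes and 3 and 10 for heat shock genes.

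Among receptors and their mediators, ESR1, the estrogen receptor, fell 1.29-fold (log2 -0.36, SE 0.04) and PGR, the progesterone receptor, fell 1.16-fold (log2 -0.21, SE 0.05, from 892 to 768 CPM). STAT5A rose 1.53-fold (log2 0.61, SE 0.09). CISH, a STAT5-induced inhibitor of cytokine signalling, fell 1.29-fold (log2 -0.36, SE 0.08). The prolactin receptor gene PRLR (log2 0.01, SE 0.05) and STAT5B (log2 -0.01, SE 0.05) did not pass. With an assumed coefficient of variation of 10%, 3123 genes were called and the calls of PGR (-0.22) and CISH (-0.37) ended.

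The second comparison, prolactin against vehicle, asked what prolactin changed alone. Feedback inhibitors of cytokine and growth factor signalling were among the genes that rose. SOCS2, a STAT5-induced suppressor of cytokine signalling, had 3 counts over the vehicle libraries and 167 with prolactin, a ratio of 60.2 (95% counting interval 20.2 to 295). CISH rose from 39.8 to 79.5 CPM (SE 0.07 on the log2 scale, n = 3 libraries per group), and SPRY4, an inhibitor of receptor tyrosine kinase signalling, rose 2.93-fold (log2 1.55, SE 0.15). The EGF receptor ligand AREG rose 2.57-fold, from 183 to 473 CPM (log2 1.36, SE 0.05), and GRIK1, a kainate-type glutamate receptor subunit, rose 4.61-fold (log2 2.20, SE 0.12). MAML2, a Notch coactivator, fell 2.38-fold (log2 -1.25, SE 0.17), and the adaptor gene GRB7 fell 1.96-fold (log2 -0.97, SE 0.14).

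By the edgeR quasi-likelihood test, 2225 genes (15.1%) were called, 1224 higher and 1001 lower. With total-count scaling the larger share was lower, with 1038 genes higher and 1219 lower. The median fold of the genes called with TMM was 1.22, and 105 changed at least 2-fold (76 higher and 29 lower). Among the largest increases were the transcription factor gene EGR1 (4.37-fold), the calpain gene CAPN8 (4.34-fold), the atypical cadherin gene FAT4 (4.05-fold) and ABCG2, a multidrug efflux transporter (3.67-fold). RANBP3L (2.30-fold), NXPH3 (2.50-fold), EPS8L3 (2.70-fold) and CSRNP3 (2.53-fold) were among the largest decreases. The DESeq2 Wald test called 867 genes, and 333 were called with an assumed coefficient of variation of 10%.

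ERK feedback genes formed the list that rose most clearly, with 12 up, 1 down and 6 not passed of 19 (13 and 1 when adjusted over the list alone; camera adjusted p = 1.23e-17; adjusted p = 0.00132 with an estimated correlation). SPRED1 rose 1.84-fold and the phosphatase gene DUSP4 1.73-fold, from 76.2 to 132 CPM. Immediate early genes were 11 up and 11 not passed of 22, with the same counts over the list alone (camera adjusted p = 5.18e-08; adjusted p = 0.00195 with an estimated correlation). IER3 (log2 0.51, SE 0.06) and KLF10 (log2 0.51, SE 0.07) rose, although 26.5% of the exonic bases of IER3 are shared with an antisense gene. Prolactin and STAT5 targets were 12 up, 2 down and 8 not passed of 22 (14 and 2 over the list alone; camera adjusted p = 4.19e-07; adjusted p = 0.0248 with an estimated correlation). Basal keratins and stem-like markers were 6 up and 5 not passed of 11 (6 up and 1 down over the list alone; camera adjusted p = 0.000238; adjusted p = 0.0464 with an estimated correlation), with CD44 at 0.43 (SE 0.06).

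Further lists were called with the preset correlation alone. Luminal markers were 7 up and 2 down of 20 (8 and 2 over the list alone; camera adjusted p = 0.000582; adjusted p = 0.297 with an estimated correlation), with KRT18 at 0.36 (SE 0.04) and the transcription factor TFAP2C at 0.32 (SE 0.04). Heat shock genes were 7 up and 1 down of 19 (8 and 1; camera adjusted p = 0.00223; adjusted p = 0.108 with an estimated correlation). Interferon-stimulated genes were 5 up and 17 not passed of 22, the same over the list alone (camera adjusted p = 0.0177; adjusted p = 0.336 with an estimated correlation), with GBP1 2.71-fold and GBP2 1.75-fold higher, and their median of 0.01 was -0.01 with total-count scaling. Of 24 G2/M genes 4 fell and 0 rose, the same over the list alone (camera adjusted p = 0.0177; adjusted p = 0.336 with an estimated correlation). Progestin targets were 8 up and 3 down of 28 (9 and 4 over the list alone), estrogen receptor targets 6 up and 2 down of 25 and housekeeping genes 2 up and 0 down of 15 (both the same over the list alone), each at a camera adjusted p of 0.0367. These 3 were at an adjusted p = 0.297, 0.339 and 0.121 with an estimated correlation. The other 8 lists had camera adjusted p of 0.0631 to 0.953.

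ESR1 fell 1.16-fold with prolactin (log2 -0.21, SE 0.04), and PRLR (0.03, SE 0.05), STAT5A (0.02, SE 0.11) and STAT5B (0.04, SE 0.05) did not pass. The calls of PGR (log2 0.14, SE 0.05) and FKBP5 (log2 -0.14, SE 0.04) were not stable, and each ended when any 1 of several libraries was left out. FKBP5 was -0.11, -0.13, -0.12 and -0.15 and not called without vehicle 1, vehicle 3, prolactin 1 or prolactin 2. PGR was 0.07 without vehicle 2, and its call also ended at 0.12 to 0.16 without vehicle 3, any R5020 library, any prolactin library or combination library 2, and at 0.14 and 0.12 with DESeq2 and total-count scaling.

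Genes called for both hormones against vehicle were compared to see whether the hormones acted on shared genes. TMEM106A, a membrane protein, rose with R5020 (log2 1.24, SE 0.08) and with prolactin (0.97, SE 0.08), as did the Notch ligand DLL1 (1.33 and 1.39, SE 0.12 each). DLG2, a synaptic scaffold protein, fell with both (-2.61, SE 0.12, and -1.11, SE 0.08), as did ANK3, which anchors membrane proteins to the cytoskeleton (-1.24, SE 0.06, and -0.58, SE 0.05). NEDD9, a focal adhesion scaffold, rose with R5020 (1.60, SE 0.09) and fell with prolactin (-1.09, SE 0.14). AREG fell with R5020 (-1.63, SE 0.06) and rose with prolactin (1.36, SE 0.05), and in the combination was close to vehicle (-0.16, SE 0.05). The transcription factor RUNX1 moved in the same way as AREG (-0.54, SE 0.04, and 0.68, SE 0.04). In all, 1460 genes were called for both hormones, 1006 of them (68.9%) in the same direction (505 higher and 501 lower, against 268.8 and 199.7 for independent lists). Opposite directions were seen for 454, of which 199 rose with R5020 and 255 rose with prolactin (219.9 and 244.2 for independent lists). With total-count scaling 23.1% of the genes called for both rose with both, against 34.6% with TMM. In 20 simulations all groups were drawn unchanged, with simulated vehicle libraries shared by both comparisons. Each comparison called at most 1 gene there, so the count of 0 genes called for both was fixed in advance and cannot judge the overlap. The covariance of log2 fold changes was 0.0280 observed and 0.0138 simulated. The 3 vehicle libraries serve both comparisons and cannot be divided into separate controls of at least 2 each, so part of the excess in the same direction may come from shared controls. The DESeq2 Wald test gave 554 shared genes, and 202 were shared with an assumed coefficient of variation of 10%.

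The combination against vehicle measured the joint change. SCNN1G rose 42.7-fold (log2 5.42, SE 0.40, n = 3 libraries per group) and PKP1, a desmosomal plakophilin, 38.9-fold (log2 5.28, SE 0.69). RBBP8NL fell 13.3-fold (log2 -3.73, SE 0.37), and CYP1A1, the aryl hydrocarbon receptor target that oxidises aromatic compounds, fell 12.4-fold (log2 -3.64, SE 0.55). Of 24 G2/M genes 20 fell, 4 did not pass and 0 rose, over all genes and over the list alone (camera adjusted p = 4.03e-05; adjusted p = 0.162 with an estimated correlation), with the spindle gene HMMR at -0.49 (SE 0.05) and the kinetochore motor CENPE at -0.40 (SE 0.04). Progestin targets were 22 up and 1 down of 28 (camera adjusted p = 5.65e-16; adjusted p = 0.0979 with an estimated correlation), ion transport genes 9 up and 1 down of 13 (7.08e-06; adjusted p = 0.123 with an estimated correlation), and basal and stem-like markers 6 up and 2 down of 11 (0.00832; adjusted p = 0.162 with an estimated correlation), all with the same counts over the list alone. CD44 rose 3.56-fold. FKBP5 (0.76, SE 0.04), CISH (0.58, SE 0.07) and STAT5A (0.45, SE 0.10) rose, ESR1 (-0.54, SE 0.04) and PGR (-0.23, SE 0.05) fell, and PRLR and STAT5B did not pass. The test called 7230 genes (49.0%), 3729 higher and 3501 lower, with 1114 at least 2-fold. With total-count scaling 33.7% of the calls were higher, against 51.6% with TMM. An assumed coefficient of variation of 10% left 3769 calls and ended that of PGR.

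The combination against R5020 gave the effect of prolactin in cells that also received the progestin. SOCS2 rose from 1 count to 32, a ratio of 34.1 (95% counting interval 5.70 to 1388). SERPINA3, a serine protease inhibitor, rose 3.14-fold from 27.0 to 84.7 CPM (log2 1.65, SE 0.08, n = 3 libraries per group), although 37.6% of its exonic bases lie in another annotated gene. SPRY4 rose 4.50-fold (log2 2.17, SE 0.22), the ephrin receptor gene EPHA2 3.25-fold (log2 1.70, SE 0.13) and AREG 2.78-fold (log2 1.48, SE 0.07). MAML2 fell 2.53-fold (log2 -1.34, SE 0.23), and KLHL24, an adaptor of a ubiquitin ligase, fell 2.21-fold (log2 -1.15, SE 0.08).

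ERK feedback genes rose again, 10 up, 1 down and 8 not passed of 19 (13 and 1 over the list alone; camera adjusted p = 6.61e-11; adjusted p = 0.0119 with an estimated correlation), with DUSP4 at 0.54 (SE 0.06). Heat shock genes were 10 up and 0 down of 19 (14 and 0; camera adjusted p = 1.1e-08; adjusted p = 0.0119 with an estimated correlation), among them the small heat shock protein genes HSPB1 (0.37, SE 0.04) and CRYAB (0.70, SE 0.13). Of 24 G1/S genes, 12 fell, 11 did not pass and CCND1, the cyclin D1 gene, rose (1 up and 13 down over the list alone; camera adjusted p = 1.7e-06; adjusted p = 0.0472 with an estimated correlation). The S-phase transcription factor E2F2 fell 1.51-fold (log2 -0.60, SE 0.09) and the replication licensing gene MCM6 fell 1.20-fold (log2 -0.26, SE 0.05). Immediate early genes were 7 up and 0 down of 22 (10 and 0; camera adjusted p = 0.000119; adjusted p = 0.0172 with an estimated correlation) and STAT5 targets 9 up and 2 down of 22 (11 and 2; 0.000447; adjusted p = 0.0472 with an estimated correlation). Milk and alveolar differentiation genes were 5 up and 1 down of 11, the same over the list alone (camera adjusted p = 0.000349; adjusted p = 0.0183 with an estimated correlation). ELF5 (0.59, SE 0.06) and ID2, an inhibitor of basic helix-loop-helix factors (0.57, SE 0.08), were among those that rose, as was MUC1 (0.95), the gene whose counts varied within the combination group. Interferon-stimulated genes were 8 up and 0 down of 22 (9 and 0; camera adjusted p = 4.31e-07; adjusted p = 0.0665 with an estimated correlation), with GBP1 3.62-fold higher. Housekeeping genes were 2 up and 1 down of 15, the same over the list alone (camera adjusted p = 0.00813; adjusted p = 0.0472 with an estimated correlation), with ACTB at 0.42 (SE 0.05). G2/M genes (0 up and 5 down of 24; 0 and 6 over the list alone), basal and stem-like markers (6 up and 1 down of 11), luminal markers (6 up and 4 down of 20) and estrogen receptor targets (6 up and 2 down of 25; 7 and 2) had camera adjusted p of 0.000349, 0.00226, 0.00281 and 0.00769. With an estimated correlation these were an adjusted p = 0.182, 0.0663, 0.259 and 0.233, and the median of the estrogen receptor targets turned from 0.03 to -0.00 with total-count scaling. In all 2171 genes (14.7%) were called, 1090 higher and 1081 lower, 73 of them at least 2-fold. CISH rose (0.94, SE 0.08) and ESR1 fell (-0.18, SE 0.04), while PGR, FKBP5, PRLR, STAT5A and STAT5B did not pass. With total-count scaling 35.8% of the calls were higher, against 50.2% with TMM. The DESeq2 Wald test called 850 genes and an assumed coefficient of variation of 10% left 265, without MCM6, HSPB1 and ESR1.

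**Figure D2:**
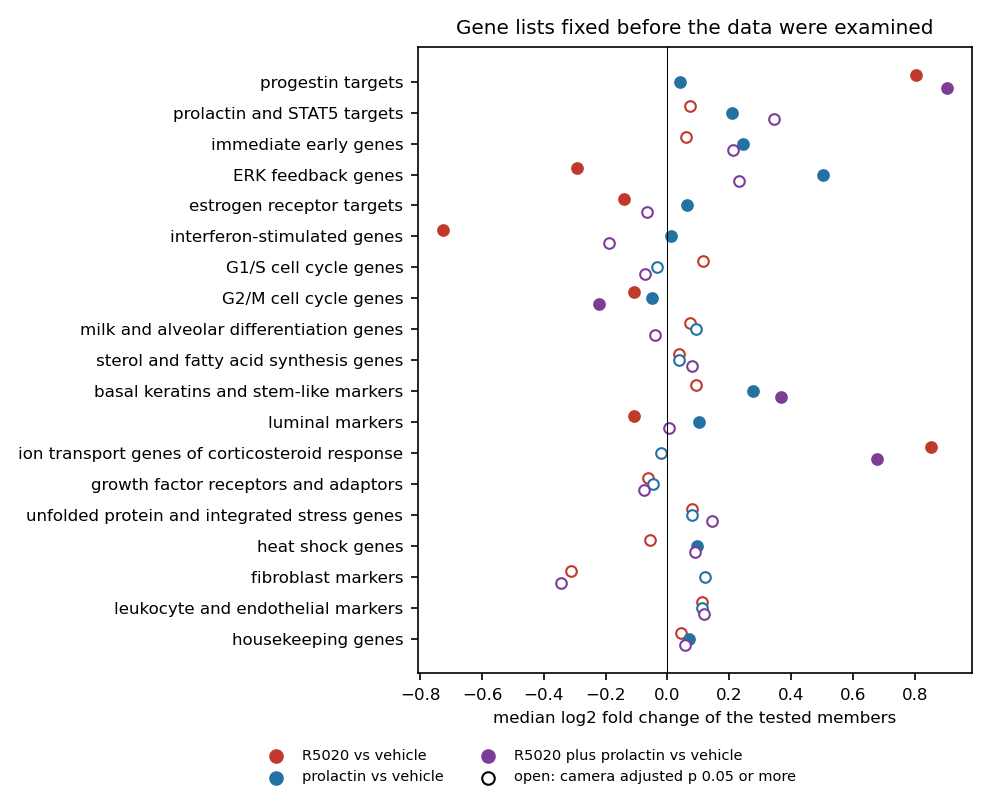
Median log2 fold change of each of the 19 gene lists for R5020, prolactin and the combination against vehicle, with filled points where the camera test was called at the preset correlation. ERK feedback genes lie at -0.29 for R5020 and 0.50 for prolactin, and interferon-stimulated genes at -0.73 for R5020.

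The combination against prolactin gave the effect of R5020 in cells that also received prolactin. KCNC1 rose 42.2-fold (SE 0.34 on the log2 scale, n = 3 libraries per group) and TSC22D3 6.21-fold (log2 2.63, SE 0.09). CDKN1C, a cyclin-dependent kinase inhibitor, went from 3 counts to 187, a ratio of 62.6 (95% counting interval 21.1 to 306). GRIK1, which prolactin had raised, fell 16.8-fold (log2 -4.07, SE 0.23), and SOCS2 fell 5.15-fold (log2 -2.37, SE 0.28). CISH fell 1.34-fold (log2 -0.42, SE 0.06), PGR 1.29-fold (log2 -0.37, SE 0.05) and ESR1 1.26-fold (log2 -0.33, SE 0.04), while FKBP5 (0.90, SE 0.04) and STAT5A (0.44, SE 0.10) rose and PRLR and STAT5B did not pass. Progestin targets were 21 up and 1 down of 28, the same over the list alone (camera adjusted p = 5.57e-16; adjusted p = 0.00775 with an estimated correlation), and ion transport genes 9 up and 1 down of 13 (10 and 2; 4.33e-07; adjusted p = 0.0528 with an estimated correlation). Interferon-stimulated genes (1 up and 12 down of 22), estrogen receptor targets (6 up and 13 down of 25), ERK feedback genes (2 up and 10 down of 19; 2 and 11 over the list alone), G2/M genes (0 up and 16 down of 24) and luminal markers (2 up and 11 down of 20; 3 and 11) lay lower. Their camera adjusted p were 0.00043, 0.000751, 0.000836, 0.000863 and 0.00759, and with an estimated correlation an adjusted p = 0.337, 0.337, 0.097, 0.343 and 0.555. The test called 5745 genes (38.9%), 2984 higher and 2761 lower, 951 of them at least 2-fold. With total-count scaling 34.6% of the calls were higher, against 51.9% with TMM.

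Each effect was then compared without and with the other hormone, in contrasts that share no library. For R5020, HSD11B2 was at 2.14 without prolactin and 2.17 with it. Of the 6183 genes called for R5020 alone, 4425 (71.6%) were called in the same direction with prolactin (2416 higher and 2009 lower, against 655.4 and 550.8 for independent lists) and 25 in the opposite one. Over the 7478 genes called in either, Pearson r across genes was 0.915 and the slope 0.886. For prolactin, AREG was at 1.36 without R5020 and 1.48 with it, and SPRY4 at 1.55 and 2.17. Of the 2225 genes called for prolactin alone, 950 (42.7%) were called in the same direction with R5020 (549 higher and 401 lower, against 90.44 and 73.35) and 21 in the opposite one, with r = 0.642 and a slope of 0.569 over 3425 genes. Noise in the effect without the other hormone lowers such a slope, and changes that the test misses lower the shared percentage. Called genes changed less with prolactin (median fold 1.22) than with R5020 (1.33). The lower values for prolactin are therefore not a measure of how far R5020 reduced its effect. With total-count scaling 37.8% of the shared R5020 calls were higher, against 54.6% with TMM, and 43.5% of the shared prolactin calls, against 57.8%. The DESeq2 Wald test gave 355 shared prolactin calls, and 100 were shared with an assumed coefficient of variation of 10%.

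**Figure D3:**
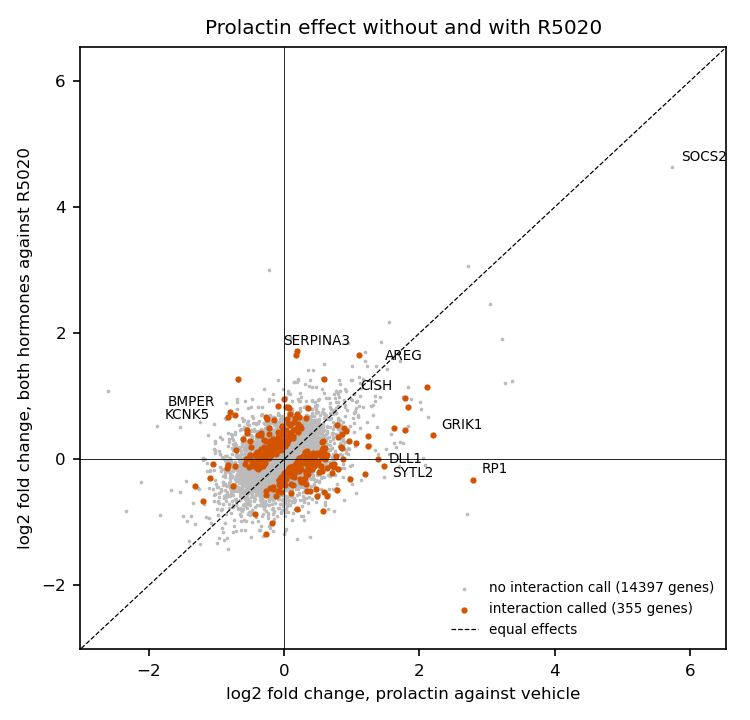
Log2 fold change of prolactin without R5020 (x axis) and with R5020 (y axis) for the 14752 tested genes, with the 355 genes called for the interaction in orange. SERPINA3 lies far above the diagonal (interaction log2 1.48) and SYTL2 far below it (interaction log2 -1.59), while CISH lies on it (-0.06).

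The interaction asked whether either hormone changed the effect of the other. SERPINA3 stood at 14.1 CPM in vehicle, 27.0 with R5020, 15.8 with prolactin and 84.7 with both, an interaction of 1.48 on the log2 scale (SE 0.15, n = 3 libraries per group). NYNRIN stood at 37.1, 113, 30.9 and 180 CPM (interaction 0.95, SE 0.10). SYTL2, which takes part in vesicle trafficking, stood at 28.1, 12.4, 78.4 and 11.4 CPM (interaction -1.59, SE 0.17), so that the rise with prolactin alone was not seen with R5020. The Notch ligand DLL1 stood at 11.9 CPM in vehicle, 29.8 with R5020 and 31.0 with prolactin, and with both was no higher (0.01, SE 0.09, on the log2 scale against R5020; interaction -1.38, SE 0.15). Other negative interactions were GRIK1 (-1.82, SE 0.35), the protocadherin PCDH7 (-1.40, SE 0.28), the channel-like gene TMC5 (-1.32, SE 0.22) and the metalloreductase STEAP4 (-1.29, SE 0.28), and positive ones were BMPER, a BMP-binding protein (1.55, SE 0.30), and KCNK5 (1.43, SE 0.22).

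The edgeR quasi-likelihood test called 355 genes (2.41%), 163 with a positive and 192 with a negative interaction, 21 of them at least 2-fold, at a median of 1.30-fold. In terms of prolactin, 99 of the 355 rose without R5020 and were not called with it, and 51 fell without it and were not called with it. Another 74 rose and 53 fell only in the calls with R5020, and 21 changed direction. In terms of R5020, 136 rose and 62 fell both without and with prolactin, and 25 changed direction. The alveolar factor ELF5 had a positive interaction (0.44, SE 0.08) and KLF4 a negative one (-0.57, SE 0.11). CISH (-0.06, SE 0.10), PGR (-0.15, SE 0.07), ESR1 (0.03, SE 0.06), PRLR (-0.11, SE 0.07), STAT5A (-0.17, SE 0.14), STAT5B (0.01, SE 0.07) and FKBP5 (0.12, SE 0.06) did not pass. G1/S genes had a lower median interaction of -0.12 (camera adjusted p = 5.03e-05; adjusted p = 0.219 with an estimated correlation) and interferon-stimulated genes a higher one of 0.21 (camera adjusted p = 0.000533; adjusted p = 0.416 with an estimated correlation), although 0 members of either passed by edgeR over all genes or over the list alone. Heat shock genes were 3 up and 0 down of 19 (4 and 0 over the list alone; camera adjusted p = 0.0294; adjusted p = 0.319 with an estimated correlation), among them HSPA1A (0.31, SE 0.06) and its near-identical paralog HSPA1B (0.26, SE 0.06), between which shared reads cannot be assigned with certainty. Milk and alveolar genes were 1 up (ELF5) and 0 down of 11, the same over the list alone (camera adjusted p = 0.0299; adjusted p = 0.219 with an estimated correlation). The DESeq2 Wald test called 96 genes, and 20 were called with an assumed coefficient of variation of 10%, without ELF5, KLF4, HSPA1A and HSPA1B.

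**Figure D4:**
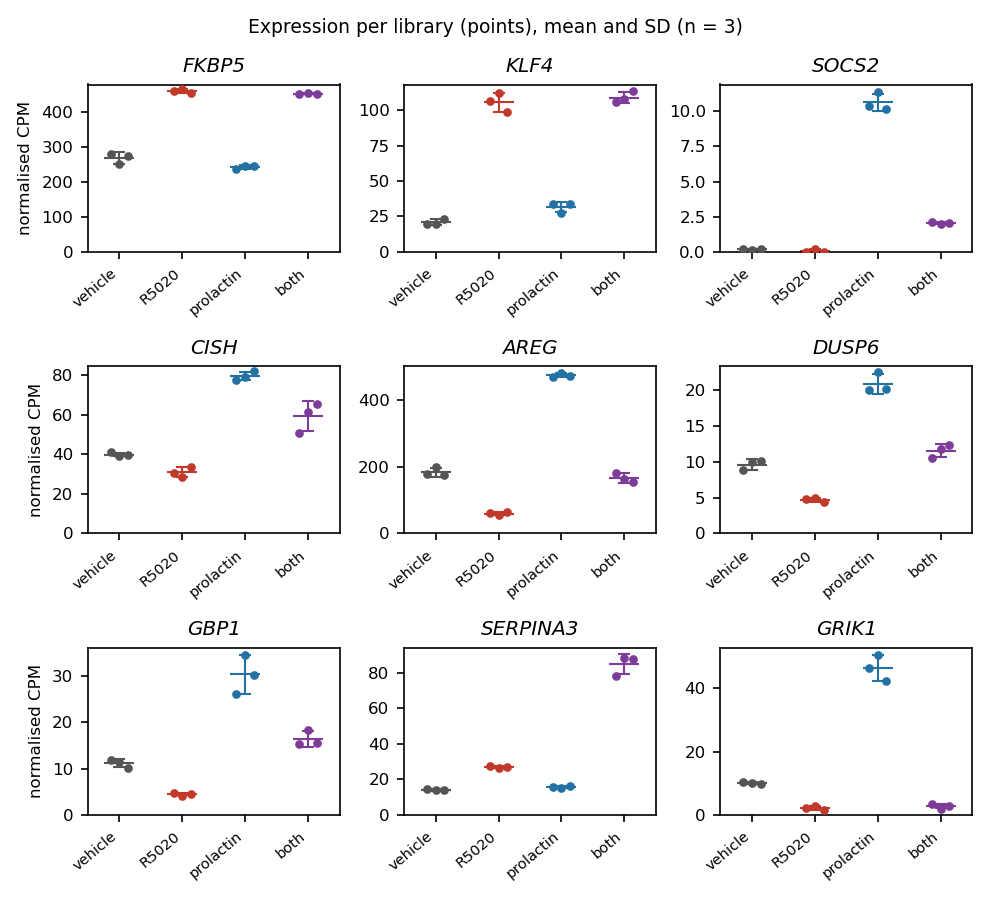
Normalised CPM of 9 genes in each of the 12 libraries, by group, with the group mean and SD as bars (n = 3). FKBP5 and KLF4 are high in both groups with R5020, CISH and SOCS2 are highest with prolactin alone, and SERPINA3 is highest with both hormones (84.7 CPM).

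Markers of other cell types were measured in the same libraries, with CPM in this paragraph taken from total counts without TMM factors. Of the fibroblast markers, COL1A1 was at 42.8 to 55.0 CPM and ACTA2 at 16.5 to 26.2 CPM in the group means, and HLA-DRA, a leukocyte marker, was at 8.57 to 13.0 CPM. With R5020, 3 of the 4 fibroblast markers tested fell and 0 rose, among them COL1A1 (log2 -0.25, SE 0.07). ACTA2 fell to log2 -0.38 (SE 0.11), and its call ended with an assumed coefficient of variation of 10%, while 38.3% of its exonic bases are shared with an antisense gene. Of 5 leukocyte and endothelial markers tested, 2 rose and 1 fell with the combination, against vehicle and against prolactin. The other markers of fibroblasts, leukocytes and endothelium lay at 5.67 CPM or less in every group mean.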

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

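The tests of noise in the vehicle libraries, of how genes were selected, of addition on the CPM scale and of the makeup of the splits were chosen only after the result was seen, and each pattern was first noticed in these data. Singled out here are results in which the effect of 1 hormone differed without and with the other by the interaction test. The interaction was called for 355 genes. Prolactin changed 21 genes in opposite directions without and with R5020, and R5020 changed 25 genes in opposite directions without and with prolactin. Several of these 25 are unnamed loci or long noncoding RNA genes with like values, such as LINC01001 (-0.20 without and 0.24 with prolactin) and LINC01002 (-0.27 and 0.24). Whether they share reads was not tested, so the 25 may not be independent.

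Among genes called for both hormones in the same direction, 127 had an interaction against that direction (87 higher and 40 lower with both hormones) and 9 along it. Noise between the shared vehicle libraries is argued against as the whole cause, within the limits of a simulation. In 20 simulations with log-additive effects and no interaction, counted at the unadjusted p of the last real call (0.00118), at most 7 such genes were seen (a mean of 3.55, and 0.15 along the direction). Effects that had not passed were set to 0 there. A mean of 776.2 simulated genes was called for both hormones in the same direction, against 1006 real ones. Vehicle noise may therefore give more such genes than were simulated. Effects that add on the CPM scale are argued against for genes that rose, taken as a set. Genes called in 8 libraries were measured in the 4 held out, over 3 held-out sets and 2 scalings. The median ratio of the change with both hormones to the sum of the single changes was at most 0.772 (95% bootstrap interval 0.676 to 0.812). For genes that fell the median ratio was up to 0.747 (0.587 to 0.936). Addition is argued against there too, since 2 decreases that add give an interaction along their direction. It gives 0 of these 40 calls (39 with total-count scaling), of which the threshold allows 17.8 to be false. How the genes were selected met its prediction as a cause of the direction, but the test cannot show that it was the cause. The contrasts used there share the combination libraries with the interaction, which favours calls along the direction. Among genes called in the same direction in the presence of the other hormone, 8.89% of 90 interaction calls ran against it (95% Wilson interval 4.57% to 16.6%). The direction thus depends on which contrasts call the genes, and is not by itself a result about how the hormones combine. A shift common to the 3 vehicle libraries stays open. Saturation of abundant genes could not be decided either, with 39.2% of the 127 genes above 100 reads per kb of transcript (31.1% to 48.0%) against 31.9% of all tested genes, and a shared limit on what both hormones can reach may be a biological explanation that was not tested.

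Splits of the 12 libraries were counted 100 at a time, the real one included. For the interaction, 8 of 100 splits gave at least 355 genes, so chance was not excluded by this count, while 20 simulations without an interaction called at most 1 gene. The other 7 gave 361 to 500 genes and, in 1 case, 3617. These 7 were among 20 splits that kept whole either the 2 groups without R5020 or the 2 groups with it, while 79 splits that mixed libraries in all groups gave at most 0. A split that keeps such groups whole carries their prolactin effect into the interaction. In mixed groups the hormone effects add to the spread. The count of splits therefore cannot judge chance for the interaction in either direction. The split with 3617 genes exchanged the R5020 and combination groups whole, which reversed the prolactin effect in these cells, so it points to the structure of the samples. For the prolactin effect without and with R5020, 1 of 100 splits gave at least 950 shared genes and the highest other gave 21, and for the R5020 effect 1 of 100 gave at least 4425 and the highest other 25, so chance was excluded for both. Of the other splits 98 gave 0 for each effect, so these counts show that the groups differ and not that the effects agree. For genes called for both hormones, 2 of 100 splits gave at least 1460. The other one gave 4242 genes with the R5020 libraries as the control, several times the real count, which again points to the structure of the samples. The share of splits was under the same threshold there. This count, too, shows that the groups differ and not that the hormones act on shared genes.

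Of the genes named by rule and reported here, 42 had an interaction call, given as log2 values. In 20 of these the call held without any 1 library. Positive values were BMPER 1.55, SERPINA3 1.48, KCNK5 1.43, AASS 0.96, NYNRIN 0.95, ELF5 0.44, SCNN1A 0.35, HSPA1A 0.31, SERPINA1 0.29 and HSPA1B 0.26. Negative values were GRIK1 -1.82, SYTL2 -1.59, PCDH7 -1.40, DLL1 -1.38, TMC5 -1.32, STEAP4 -1.29, KLF4 -0.57, PHLDA1 -0.55, RAB31 -0.55 and CXCL12 -0.31. Under prolactin BMPER, KCNK5, NYNRIN, PCDH7, PHLDA1 and HSPA1A went in opposite directions without and with R5020, and under R5020 TMC5 did so without and with prolactin.

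In the other 22 genes the call ended when at least 1 library was left out, so they are given as values, each followed by its value, or its range, over the libraries that ended the call. A single library ended the call of TMEM92 1.96 (1.45), SRGAP3-AS3 1.51 (1.42), NR2F1 -1.27 (-1.11) and COL1A1 0.45 (0.32). More than 1 did so for B3GNT3 1.53 (1.24 to 1.57), C1orf116 1.01 (0.92 to 1.05), ING4 0.98 (0.74 to 0.94), RP1 -3.12 (-2.61 to -3.33), SMKR1 -1.42 (-1.30 to -1.55), TMEM121 -1.22 (-0.97 to -1.22), EDN1 0.21 (0.17 to 0.22), JUN -0.32 (-0.28 to -0.31) and SPRED1 -0.39 (-0.36 to -0.38), and for DUSP4 -0.25 (-0.23 to -0.26), LAMB3 -0.93 (-0.81 to -0.85), KRT7 0.30 (0.26 to 0.28), SPDEF -0.25 (-0.22 to -0.25), FGFR1 -0.28 (-0.23 to -0.26), IRS1 -0.22 (-0.19 to -0.21), ERBB2 0.22 (0.19 to 0.23), HSPB1 0.23 (0.20 to 0.23) and TBP -0.60 (-0.53 to -0.57). Calls ended for B3GNT3, SMKR1, TMEM121, EDN1, JUN, SPRED1, DUSP4 and KRT7 without vehicle 1. Without vehicle 2 they ended for B3GNT3, C1orf116, ING4, RP1, SMKR1, TMEM121, SPDEF, FGFR1, COL1A1 and TBP, and without vehicle 3 for C1orf116, RP1, SMKR1, EDN1, SPRED1, DUSP4, LAMB3, ERBB2 and HSPB1. They ended for B3GNT3, SMKR1, EDN1, KRT7, SPDEF and ERBB2 without R5020 1. Without R5020 2 they ended for SMKR1, TMEM121, JUN, SPRED1, DUSP4, LAMB3, SPDEF, FGFR1, IRS1 and HSPB1, and without R5020 3 for B3GNT3, ING4, SMKR1, NR2F1, TMEM121, EDN1, DUSP4, ERBB2 and HSPB1. The calls lost were TMEM92, SMKR1, TMEM121, EDN1, DUSP4, LAMB3, IRS1, ERBB2 and HSPB1 without prolactin 1. Without prolactin 2 they ended for B3GNT3, C1orf116, ING4, RP1, TMEM121, EDN1, JUN, DUSP4 and HSPB1, and without prolactin 3 for B3GNT3, C1orf116, ING4, SMKR1, EDN1, KRT7, SPDEF, ERBB2 and TBP. Others lost were B3GNT3, SRGAP3-AS3, ING4, SMKR1, EDN1, JUN, DUSP4, SPDEF, IRS1 and TBP without combination 1. Without combination 2 they ended for SMKR1, TMEM121, EDN1, DUSP4, KRT7, SPDEF, FGFR1, IRS1 and ERBB2, and without combination 3 for DUSP4, ERBB2 and HSPB1. COL1A1 also went in opposite directions under R5020. The value of RP1, which had 2 counts in vehicle and 15 with prolactin, depends on the prior count of the fit. The difference between the hormones' effects was tested for each of the 42 by the interaction itself, and groups of 3 libraries were not tested for single outlying samples.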

How the results depend on the processing

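The fit with an assumed coefficient of variation of 10%, the other form of the quasi-likelihood fit and the fits without MUC1 or without genes above 200 reads per kb were chosen only after the data had been seen. Of 659 values of named genes, 458 were called, and 62 of these lost the call without at least 1 library. Among values called in the main fit or in the other setting, 0 changed direction. Directions were not compared for values called in neither. Fits on the compared groups alone held 578 of the values, the fit without MUC1 656 and that without genes above 200 reads per kb 416. Counts of called genes stayed within 1.5 times the main count with DESeq2 or total-count scaling, limma-voom, other filters, fits on the compared groups alone, the other quasi-likelihood form, and without MUC1 or the most abundant genes. The DESeq2 Wald test gave 867 genes for prolactin against vehicle, 850 for the combination against R5020, 96 for the interaction, 554 for both hormones and 355 for the prolactin effect without and with R5020, and the cause was not tested. An adjusted p under 0.01 gave 1327, 1321, 187, 827 and 546 in the same order, as a stricter threshold must give fewer. The assumed coefficient of variation of 10% gave 3123 genes for R5020 and 333 for prolactin against vehicle, 3769 for the combination against vehicle, 265 against R5020 and 2861 against prolactin. It gave 20 for the interaction, 202 for both hormones, 2285 for the R5020 effect and 100 for the prolactin effect without and with the other hormone. That setting replaces the spread measured here, 2.35%, with a larger one. Of the 45 list tests called by camera at its preset correlation, 12 were called with an estimated correlation, which allows for genes of a list that vary together, and fry, which asks another question, called 76.

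Leaving out 1 library at a time gave 5537 to 6243 genes for R5020 and 1626 to 2273 for prolactin against vehicle, and 6548 to 7249 for the combination against vehicle. It gave 1629 to 2321 for the combination against R5020, 5085 to 5882 against prolactin, 257 to 346 for the interaction and 1084 to 1483 for both hormones. The R5020 effect without and with prolactin had 4066 to 4241 shared genes and the prolactin effect without and with R5020 had 750 to 885. With 1 library left out, its group was represented by 2. Each comparison of 2 groups allows only 10 splits of its libraries, of which 1 gave the real count, so a share under 0.05 cannot be had. The real counts were 6183, 2225, 7230, 2171 and 5745 and the highest of the other splits gave 0 in each. In simulated data at the depth and spread of these libraries 56% of the smallest changes set were recovered for R5020 against vehicle and 32% for the interaction.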

Other observations

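Gene families, the comparison of read densities between replicates and the search for repeated deposits were chosen only after the data had been seen. The 44 families were defined by gene symbols, and each was tested with camera against all other genes, adjusted over the 44.

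With prolactin, genes of the nucleolus and of ribosome assembly were higher, 26 up and 1 down of 108, at a median log2 fold change of 0.08 (camera adjusted p = 0.000783; adjusted p = 0.0178 with an estimated correlation). In cells that also received R5020 they were 24 up and 2 down with prolactin, at a median of 0.07 (0.00471; adjusted p = 0.0417 with an estimated correlation). Housekeeping genes had a median of 0.07 in each of these comparisons (camera adjusted p = 0.0367 and 0.00813), so the medians do not set this family apart from them. Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, were 9 up and 0 down of 17 with prolactin (7.52e-05; adjusted p = 0.353 with an estimated correlation), among them TARS1 (0.37, SE 0.05) and GARS1 (0.24, SE 0.04). Cytosolic ribosomal protein genes were 16 up and 0 down of 78 with prolactin in the presence of R5020, at a median of 0.11 (3.68e-09; adjusted p = 0.349 with an estimated correlation). Keratins were 7 up and 0 down of 17 there (2.02e-05; adjusted p = 0.0417 with an estimated correlation), with KRT7 at 0.52 (SE 0.05), KRT18 at 0.45 (SE 0.04) and KRT80 at 0.42 (SE 0.04). These medians kept their direction with DESeq2 and total-count scaling.

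With R5020, 9 of 14 NBPF genes rose and 0 fell, at a median of 0.39 (5.84e-06; adjusted p = 0.418 with an estimated correlation). NBPF genes are near-identical copies, so their reads are not independent, and NBPF10 (0.74, SE 0.05), NBPF20 (0.76, SE 0.06) and NBPF14 (0.77, SE 0.06) had like values. Of 19 Notch pathway genes, 3 had a negative interaction and 0 a positive one (0.00236; adjusted p = 0.245 with an estimated correlation), namely DLL1 (-1.38, SE 0.15), JAG1 (-0.72, SE 0.19) and NOTCH1 (-0.35, SE 0.07). JAG1, a Notch ligand, rose with R5020 alone (2.07, SE 0.14). PDK4, an inhibitor of pyruvate oxidation, rose with R5020 (3.38, SE 0.16).

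Of 59 protocadherin genes, cell adhesion molecules most of which lie in 3 gene clusters, 43 fell and 2 rose with R5020 (median -0.31), 13 fell and 1 rose with prolactin (median -0.18), and 47 fell and 2 rose with both (median -0.47). The 5 genes outside the clusters did not share a clear fall with R5020, at 1 up and 2 down (median -0.155, 95% bootstrap interval -1.04 to 0.869). Reads on exons that cluster members share are argued against as the whole cause, since the protocadherin beta genes, which have no exon in common, were lower at a median of -0.303 with R5020 (95% bootstrap interval -0.306 to -0.232). GC content and transcript length are argued against too, from 3546 other genes in the same GC and length bins. The medians of the bins, each counted once per protocadherin in it, had a median of 0.0245. Random draws of 1 such gene per protocadherin had medians of -0.0591 to 0.101 (95% range). Read sharing between similar sequences within the clusters was not tested, and camera gave an adjusted p of 3.63e-05 for R5020 with 0.418 under an estimated correlation. A lower output of these clusters with each hormone may be a biological explanation, which stays a hypothesis.

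Some replicates differed by less than sampling noise, with chi-square ratios of 0.830 to 2.25 and 4 of 12 pairs under 1 (0.817 to 1.84 and 7 of 12 without the gene that differed most in each pair). The median ratio of the 12 pairs was 0.994 for genes under 5 reads per kb of transcript and 0.770 at 100 to 200 reads per kb, then 0.832 at 200 to 400 and 3.44 above 400. Whether identical reads were counted once could not be decided, as the lower ratio at 100 to 200 than under 5 reads per kb in 10 of 12 pairs comes from the bins in which it was noticed. GC content could not be decided either, since the ratio was lower at high density in 37 of 60 combinations of pair and GC bin. Repeated deposit of 1 library is argued against, because the fewest genes that differed between replicates were 8.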
